A study of Mus musculus with 4 samples.

How the data were processed

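Messenger RNA was measured in 4 libraries of sorted splenic TFH cells, 2 from WT and 2 from Etv5 cKO mice. Libraries were made with a stranded poly(A) kit, per the labels' protocols. The submitters' processing notes name TopHat2 2.0.13, Cuffdiff 2.2.0 and the mouse build mm10; the order of steps, the annotation release, the strand setting and the normalization between libraries are not given in the sources used here. The deposited table has the column layout of a Cuffdiff comparison of genes, per the file headers, with annotation columns added.

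Per the file headers, both libraries of a genotype enter 1 Cuffdiff condition, and the table holds the authors' FPKM value (fragments scaled to transcript length and to the number of mapped fragments) for each gene and condition. Whether that value is a mean over libraries or comes from pooled reads is not stated. The deposited log2 fold change is Etv5 cKO over WT without a pseudocount: it differed from the log2 of the FPKM ratio by at most 4.1e-11. The authors' fold ratio (larger FPKM over smaller), a test score, a p-value and an adjusted p-value (FDR) complete each row. The smallest p-value in the deposited table is 5e-05. Genes with the status not tested carry a p-value of 1 in the deposited table. The table used here has 1 empty line, which was not analysed here. FPKM values of very short genes (small nucleolar and micro RNAs) are unstable, and overlapping or near-identical genes can share reads.

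FPKM values depend on gene length, on how reads shared by several genes are divided, and on the composition of the whole library, and they carry no counts. The depth of the libraries is therefore unknown, and no interval or detection limit was computed from it. No value per library was available, so no standard deviation, no test of the libraries by a second tool and no fit with the replicate number was possible. The tests planned before the data were examined (edgeR or limma on library values, camera and fry) could not be fitted, and the authors' own Cuffdiff test took their place. With nothing in the labels on separate mice, its p-values may measure technical spread. The direction of a gene in each library could not be checked either, although the naming rule asked for it.

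A gene was called at a deposited adjusted p below 0.05, without a minimum fold change. Before the data were examined, 23 gene lists were fixed for T cell states, signalling, metabolism, stress and other cell types, and alternative symbols were matched through the RefSeq gene table of GRCm38. Of 541 symbols in the lists 530 were found. For each list the called members were counted over all genes and adjusted over the list alone (Benjamini-Hochberg). Each list with at least 5 tested genes was compared with all other tested genes by cameraPR of limma 3.58.1 (R 4.3.3), two-sided, on the deposited test score of 11564 genes, with a preset correlation between genes of 0.01 and adjustment over 22 lists. A correlation estimated from the data, which camera can use, needs library values and could not be had; preset correlations of 0.05 and 0.1 were tried in its place. The median log2 fold change of a list was also compared with 10000 random lists matched on mean FPKM in 20 bins. Genes are not independent replicates, so these tests describe these libraries. On shuffled scores of the 11564 genes, with 5 lists shifted in each of 50 simulations, the set test recovered 11.6% of lists shifted by 0.5 SD and 78.8% of lists shifted by 1 SD, none in the wrong direction, and called 0.353% of unshifted lists. Shuffling removes any correlation between the genes of a list. These shares therefore do not give the error rate for lists of genes that vary together.

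Genes were named by a rule fixed beforehand: Etv5, Spp1, the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 FPKM (clone names, micro and small nucleolar RNAs and receptor segments left out), up to 4 genes of lowest p per list, and 12 core TFH genes. All other named genes were chosen after their values were seen, among them Lag3, Cd44, Tbx21, Gata3, Foxp3, Mki67, Hba-a1, Hba-a2, Xist and the X-linked genes named beside it. Some genes that the rule names are not reported here. Start positions were given as 1-based by adding 1 to the deposited start: 11280 of 22432 genes with a single reference symbol then matched the RefSeq start on GRCm38, the assembly behind mm10, against 676 without it. Analyses used Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives were other pseudocounts, quantile normalization, median centring, other filters, another threshold and other settings of the set test.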

Results

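Follicular helper T (TFH) cells are the CD4 T cells that help B cells in germinal centres. They were sorted from mouse spleen as CD4, CD44, CXCR5 and PD-1 positive cells, 7 days after immunization with ovalbumin in alum, and their messenger RNA was sequenced. Wild-type mice carried floxed Etv5 without Cre (WT). Conditional knockout mice (Etv5 cKO) carried the same allele with Cd4-Cre, which deletes floxed sequence in T cells. Etv5 encodes a transcription factor of the ETS family. Each genotype was represented by 2 libraries, and nothing in the labels says whether these came from separate mice. The authors' deposited table gives 1 FPKM value per gene and genotype over both libraries, so no spread between libraries could be computed and the sequencing depth is unknown. The p-values of the table's Cuffdiff test are the only measure of error, and they may reflect technical spread. The table lists 23996 genes, of which 11569 were tested and 12427 were not.

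The first question was whether the target gene was reduced. Etv5 (mm10 chromosome 16, 22381313 to 22439570, protein coding) fell from 5.24 FPKM in WT to 2.12 FPKM in Etv5 cKO in the authors' deposited table, a log2 fold change of -1.31 (Cuffdiff adjusted p = 0.0181). The transcript level in the cKO libraries was 40.4% of the WT level, and with a pseudocount of 5 the log2 fold change was -0.52. The labels do not say which exons are floxed, and a value for the whole gene does not separate transcripts that have lost them. Members of the ETS family and of the ERK feedback pathway were fixed as a list beforehand. Of its 19 tested members 15 were lower and 4 higher in Etv5 cKO in the authors' deposited table, with 0 called by Cuffdiff over all genes, 0 adjusted over the list alone and 1 below an unadjusted p of 0.05. That gene was Spry1, an inhibitor of ERK signalling, at 23.2 FPKM in WT and 16.3 FPKM in cKO (adjusted p = 0.898). As a list these genes did not pass the set test against all other genes (limma cameraPR, adjusted p = 0.0932). The call depends on the statistic, since the list passed on ranks of the test score (adjusted p = 0.0173).

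The main question was which transcripts differed between WT and Etv5-deficient TFH cells. At an adjusted p below 0.05 the authors' deposited table called 40 genes, 28 lower and 12 higher in Etv5 cKO. Among the lower genes were Spp1, Lag3, Ifng and Rgs16, and among the higher genes were Il7r, Itgb3 and a set of erythroid transcripts. The profiles were otherwise close: 78.9% of the tested genes differed by less than 0.2 on the log2 scale, and the median log2 fold change was -0.003. Of the 40 genes, 4 were Y-linked and 7 belonged to a list of erythroid genes drawn up after the table was seen. Without these, 29 called genes remained, 24 lower and 5 higher. The 5 higher genes were Il7r, Itgb3, Cd24a, Mpo and Lyz2, of which Mpo and Lyz2 belong to the fixed lists of granulocyte and myeloid markers. Of the 40 genes, 32 shared the smallest p that the table holds (5e-05), so their order by p carries no information.

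**Figure D1:**
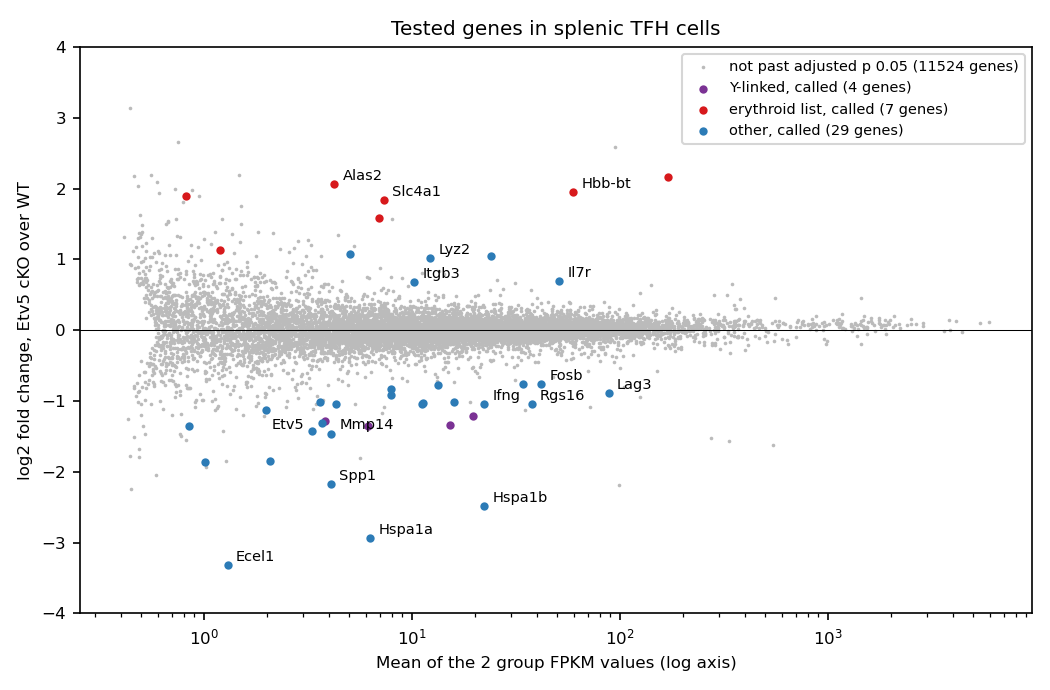
Log2 fold change (Etv5 cKO over WT, vertical) against the mean of the group FPKM values (log axis, horizontal) for 11564 tested genes, with 2 genes beyond the vertical axis; each point is 1 gene. The 7 called erythroid genes lie above 1, and Spp1, Hspa1a, Hspa1b and Ecel1 lie below -2.

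Spp1 encodes osteopontin, a secreted phosphoprotein that binds CD44 and integrins, and its protein-coding gene was named in advance. It lies on mm10 chromosome 5 from 104435111 to 104441053. In the authors' deposited table Spp1 fell from 6.68 to 1.48 FPKM, 4.51-fold (log2 fold change -2.17, Cuffdiff adjusted p = 0.0181). With pseudocounts of 1 and 5 the log2 fold change of Spp1 was -1.63 and -0.85. Itgb3, the beta chain of an integrin that binds osteopontin, rose in the authors' deposited table from 7.84 to 12.6 FPKM (log2 fold change 0.68, adjusted p = 0.0434, and 0.0900 when adjusted over every listed gene, which ends the call). Granulocyte, erythroid and platelet markers (median log2 fold change 1.32) and myeloid markers (median 0.46) were higher as lists in the same libraries. Which cells carried the Itgb3 transcripts was not tested. The 7 other tested members of the osteopontin and receptor list were not called. They included Cd44 at 95.6 and 97.7 FPKM and Itgav at 20.1 and 16.2 FPKM in WT and cKO. Adjusted over the list alone, Spp1 and Itgb3 passed. The list as a whole did not pass the set test (adjusted p = 0.369). Its median log2 fold change was 0.03, its mean was -0.16, and cameraPR gave it the direction down, except on ranks, where the direction was up.

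Ifng and Lag3 fell, while the lists of effector and helper genes went both ways. Lag3, an inhibitory receptor that binds MHC class II, fell from 115 to 61.9 FPKM in the authors' deposited table (log2 fold change -0.89, adjusted p = 0.0181). Ifng, the signature cytokine of Th1 cells, fell from 29.8 to 14.5 FPKM in the authors' deposited table (log2 fold change -1.04, adjusted p = 0.0181). Cxcr3 (83.8 and 56.1 FPKM, adjusted p = 0.231) and Il10 (9.96 and 4.72 FPKM, adjusted p = 0.249) had lower values in Etv5 cKO without passing over all genes. Adjusted over the list alone, 2 lower genes (Ifng and Cxcr3) and 1 higher gene (Ccr2, 5.91 and 9.97 FPKM) passed among the 25 tested Th1 and effector genes, and 1 lower gene (Il10) passed among the 12 tested Th2 genes. In the same libraries 19 of 20 tested myeloid and dendritic markers were higher (median log2 fold change 0.46), and which cells carried the Ccr2 transcripts was not tested. Tbx21, the Th1 master regulator, stood at 9.03 and 7.65 FPKM, and Gata3, the Th2 master regulator, at 54.3 and 59.8 FPKM. Of the Th1 and effector genes 15 were higher and 10 lower, with a median log2 fold change of 0.10, and of the Th2 genes 6 were higher and 6 lower, with a median of 0.06. Neither list passed the set test (cameraPR adjusted p = 0.970 for Th1 and effector genes and 0.191 for Th2 genes), although the Th1 median lay at the 99.9th percentile of matched random lists.

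Of the 30 tested TFH identity genes 26 were lower in Etv5 cKO in the authors' deposited table, with a median log2 fold change of -0.15, but 1 of them was called over all genes. That gene was Rgs16, a regulator of G protein signalling, which fell from 50.8 to 24.5 FPKM (log2 fold change -1.05, adjusted p = 0.0181). Adjusted over the list alone, 2 genes passed, Rgs16 and Sostdc1 (58.2 and 36.8 FPKM, adjusted p over all genes = 0.181). The cytokine Il21 stood at 66.1 and 49.7 FPKM (adjusted p = 0.999). Bcl6, the transcription factor that directs TFH differentiation, stood at 95.9 and 86.9 FPKM, and the homing receptor Cxcr5 at 183 and 158 FPKM. Pdcd1, which encodes PD-1, stood at 173 and 154 FPKM, and the costimulator Icos at 165 and 160 FPKM. The transcription factors Maf (206 and 173 FPKM), Ascl2 (10.6 and 7.78 FPKM), Tcf7 (669 and 607 FPKM) and Tox2 (94.7 and 93.4 FPKM) were not called. Nor were Sh2d1a (226 and 223 FPKM), Cd40lg (106 and 111 FPKM) and Il4 (52.1 and 56.6 FPKM). As a list the TFH genes lay lower than other genes (cameraPR adjusted p = 2.86e-07), and they did so without Rgs16 and Sostdc1 (unadjusted p = 1.10e-04). In the same libraries the granulocyte, erythroid and platelet markers had a median log2 fold change of 1.32, the myeloid markers 0.46 and the CD8 and NK markers 0.42. A list of 20 pan T cell genes, drawn up later, had a median log2 fold change of -0.086, with 14 members lower and 6 higher.

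**Figure D2:**
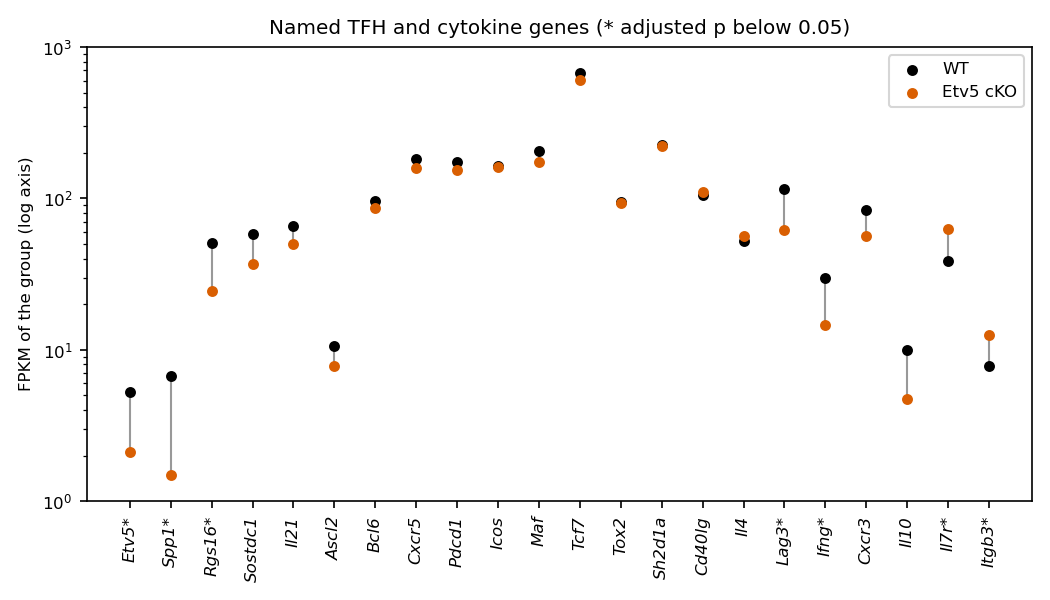
FPKM of the group (log axis) in WT (black) and Etv5 cKO (orange) for named TFH, cytokine and receptor genes, 1 value per genotype and no error bars because the table gives none; an asterisk marks an adjusted p below 0.05. Etv5, Spp1, Rgs16, Lag3 and Ifng fell, Il7r and Itgb3 rose, and the points of Bcl6, Icos and Tox2 nearly overlap.

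Lists of other T cell states passed the set test with few called members. All 9 tested Th17 genes had higher values in Etv5 cKO in the authors' deposited table, with a median log2 fold change of 0.47, and the list passed the set test (cameraPR adjusted p = 9.58e-08). None of them was called by Cuffdiff over all genes, 4 were below an unadjusted p of 0.05, and 2 passed adjusted over the list alone. Among these was Il1r1, a receptor of interleukin-1 (13.6 and 19.1 FPKM, adjusted p over all genes = 0.863). Myeloid markers, with a median log2 fold change of 0.46, were higher in the same libraries. Regulatory T and follicular regulatory genes lay lower as a list (median log2 fold change -0.17, adjusted p = 0.00140), with 13 of 19 members lower, 0 called by Cuffdiff, 0 adjusted over the list alone and 3 below an unadjusted p of 0.05. With a preset correlation of 0.1 that list's adjusted p was 0.0617. Its members included Nrp1 (45.0 and 32.9 FPKM) and Nt5e (108 and 78.8 FPKM), while Foxp3, which defines regulatory T cells, stood at 65.3 and 66.3 FPKM. Il7r, the interleukin-7 receptor of naive and memory T cells, rose from 38.8 to 62.8 FPKM in the authors' deposited table (log2 fold change 0.69, adjusted p = 0.0351, and 0.0727 when adjusted over every listed gene, which ends the call). It was the 1 called gene, over all genes and adjusted over the list alone, among 19 naive and recirculation genes, 13 of which were higher. That list passed at the preset correlation of 0.01 (adjusted p = 0.00391) and not at 0.1 (adjusted p = 0.0974).

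Some heat shock and immediate early genes fell in Etv5 cKO. Hspa1a and Hspa1b, near-identical neighbouring genes for inducible HSP70 whose reads are hard to assign to either, fell from 11.1 to 1.46 and from 37.6 to 6.71 FPKM in the authors' deposited table. These were log2 fold changes of -2.93 and -2.49, each with an adjusted p of 0.0181, and with a pseudocount of 5 they were -1.32 and -1.86. The other 22 tested members of the heat shock and unfolded protein list were not called, and 2 genes passed adjusted over the list alone. Hsph1 (46.6 and 34.3 FPKM) and Dnajb1 (62.6 and 46.8 FPKM) had unadjusted p of 0.0145 and 0.0200. The list passed the set test (cameraPR adjusted p = 2.51e-09), and without Hspa1a and Hspa1b its unadjusted p was 0.0487. Fosb, an AP-1 subunit induced by stimulation, fell from 52.5 to 31.0 FPKM in the authors' deposited table (log2 fold change -0.76, adjusted p = 0.0434, and 0.0900 over every listed gene, which ends the call). Of the 27 tested genes of the T cell receptor signalling and immediate early list 19 were lower, among them Fos (180 and 121 FPKM, adjusted p = 0.606), Egr2 (38.4 and 28.6 FPKM) and Jun (36.3 and 28.0 FPKM), and 1 gene passed adjusted over the list alone. The list passed the set test at the preset correlation of 0.01 (adjusted p = 0.0388) and not at 0.1 (adjusted p = 0.301). Ier5l and Npas4, 2 further called genes, fell from 15.0 to 7.27 and from 15.3 to 7.45 FPKM. Over every listed gene the Cuffdiff adjusted p of Ier5l was 0.0900, which ends its call, while Npas4 kept its call.

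The remaining called genes that were lower in the authors' deposited table belong to no list. They included the receptor Igf1r (10.4 and 5.52 FPKM), the membrane metalloprotease Mmp14 (5.97 and 2.17 FPKM), the peptide transporter Slc15a2 (16.9 and 9.88 FPKM) and the phosphatase Ptpn5 (10.2 and 5.75 FPKM). Ecel1, a gene of low level, fell from 2.36 to 0.237 FPKM (log2 fold change -3.32, adjusted p = 0.0181), and the Ecel1 log2 fold change was -0.49 with a pseudocount of 5. Kirrel3, Esm1, Fam84a, Fbn2, Tshz2, Cpne7, Slc37a2, Mid1 and Gpm6b also fell. Of these, Esm1, Cpne7 and Slc37a2 lost their call over every listed gene (Cuffdiff adjusted p = 0.0900 each). For the genes of low level in this paragraph the fold change shrank with a pseudocount of 5. On the log2 scale it was -0.61 for Mmp14, -0.53 for Fam84a, -0.48 for Esm1 and -0.47 for Cpne7. It was -0.41 for Slc37a2, -0.31 for Tshz2, -0.28 for Kirrel3 and -0.18 for Fbn2. These genes, and Lag3, Npas4, Uty, Ank1 and Epb4.2, are outside the naming rule and were chosen after their values were seen.

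Genes of cell division, mitochondrial respiration and sterol synthesis had slightly higher values. Of 40 proliferation genes 39 were higher in Etv5 cKO in the authors' deposited table, with a median log2 fold change of 0.23, and the list passed the set test (cameraPR adjusted p = 4.13e-10). Cuffdiff called 0 of them over all genes, 0 adjusted over the list alone and 1 at an unadjusted p below 0.05, which was Ube2c (49.3 and 64.9 FPKM). The proliferation marker Mki67 stood at 32.5 and 38.1 FPKM. The cholesterol genes (21 of 22 higher, median 0.15), the oxidative phosphorylation genes (37 of 38 higher, median 0.09) and the ribosomal protein genes (39 of 40 higher, median 0.08) passed at the preset correlation of 0.01. Their adjusted p values there were 5.57e-04, 0.00344 and 0.0247. At a correlation of 0.1 none of the 3 passed (adjusted p = 0.0555, 0.175 and 0.301). The interferon response genes behaved alike (23 of 30 higher, median 0.10, adjusted p = 0.0247, and 0.293 at a correlation of 0.1). Cuffdiff called 0 genes of these 4 lists over all genes and 0 adjusted over the list alone, and 1, 0, 0 and 2 of them were below an unadjusted p of 0.05. Glycolysis genes (16 of 24 higher, adjusted p = 0.105) and regulators of PI3K, AKT and mTOR (10 of 23 higher, adjusted p = 0.970) did not pass, with 0 called by Cuffdiff in either list, 0 adjusted over the list alone, and 1 and 0 below an unadjusted p of 0.05. On ranks the glycolysis list passed (adjusted p = 0.0277). The PI3K list had a median log2 fold change of -0.0064 and a mean of 0.0037. Most members of the mixed granulocyte, erythroid and platelet list (10 of 12) and of the myeloid list (19 of 20) were higher in the same cKO libraries.

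Markers of other blood cells had the largest median fold change of the lists. Among granulocyte, erythroid and platelet markers, 5 of the 12 tested genes were called higher in the authors' deposited table and 6 passed adjusted over the list alone, with a median log2 fold change of 1.32 (cameraPR adjusted p = 1.01e-32). Of these 12 genes 10 were higher and 2 lower, the lowest with a log2 fold change of -1.20. The erythroid list drawn up later holds 6 of them. The beta-globin genes Hbb-b1 and Hbb-bs, counted together, rose from 62.1 to 279 FPKM and Hbb-bt rose 3.87-fold from 24.6 FPKM, in each case with an adjusted p of 0.0181. The alpha-globin genes Hba-a1 and Hba-a2, counted together, stood at 26.8 FPKM in WT and 162 FPKM in Etv5 cKO. They were not called, although their log2 fold change of 2.59 was the largest of the list. Alas2, the erythroid enzyme of haem synthesis, rose from 1.63 to 6.83 FPKM in the authors' deposited table. The red cell membrane genes Slc4a1 (3.21 to 11.4 FPKM), Ank1 (0.750 to 1.64 FPKM) and Epb4.2 (0.347 to 1.29 FPKM) rose as well. At these low levels the log2 fold changes depend on the pseudocount, and with 5 they were 0.83 for Alas2, 0.23 for Epb4.2 and 0.21 for Ank1. Mpo, a granule enzyme of neutrophil precursors, rose from 3.24 to 6.86 FPKM. Cd24a, which is expressed by erythroid precursors and B cells among others, rose from 15.5 to 32.2 FPKM. Lyz2, the lysozyme of myeloid cells, rose from 8.12 to 16.4 FPKM in the authors' deposited table (adjusted p = 0.0434, and 0.0900 over every listed gene, which ends the call). It was the 1 called gene of 20 tested myeloid and dendritic markers, of which 19 were higher (median log2 fold change 0.46, cameraPR adjusted p = 3.57e-15) and 6 passed adjusted over the list alone, among them C1qb (log2 fold change 0.58). Of the CD8, NK and unconventional T markers 9 of 11 were higher (median 0.42, adjusted p = 5.57e-04), with 0 called by Cuffdiff, 0 adjusted over the list alone and 2 below an unadjusted p of 0.05. B cell markers (9 of 12 higher, adjusted p = 0.126) and plasma cell markers (5 of 7 higher, adjusted p = 0.569) did not pass the set test. The B cell list, with a median log2 fold change of 0.18, did pass on ranks (adjusted p = 0.0200) and on log2(FPKM + 1) fold changes (adjusted p = 0.0425). The 2 tested stromal and endothelial markers, Pecam1 and Igfbp7, were too few for it.

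Sex-linked transcripts also differed. The 4 called Y-linked genes fell by a similar factor in the authors' deposited table, each with an adjusted p of 0.0181. Ddx3y fell from 21.8 to 8.60 FPKM, Eif2s3y from 27.4 to 11.8 FPKM, Kdm5d from 8.80 to 3.45 FPKM and Uty from 5.41 to 2.23 FPKM. With a pseudocount of 5 the log2 fold changes of Kdm5d and Uty were -0.71 and -0.53. Xist, the RNA that silences 1 X chromosome in female cells, was present in both groups, at 110 FPKM in WT and 172 FPKM in Etv5 cKO (unadjusted p = 0.0437, adjusted p = 0.999). The X-linked genes Kdm6a, Kdm5c, Eif2s3x and Ddx3x, which escape that silencing, had log2 fold changes of 0.15, 0.14, 0.18 and 0.12, none of which passed.

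**Figure D3:**
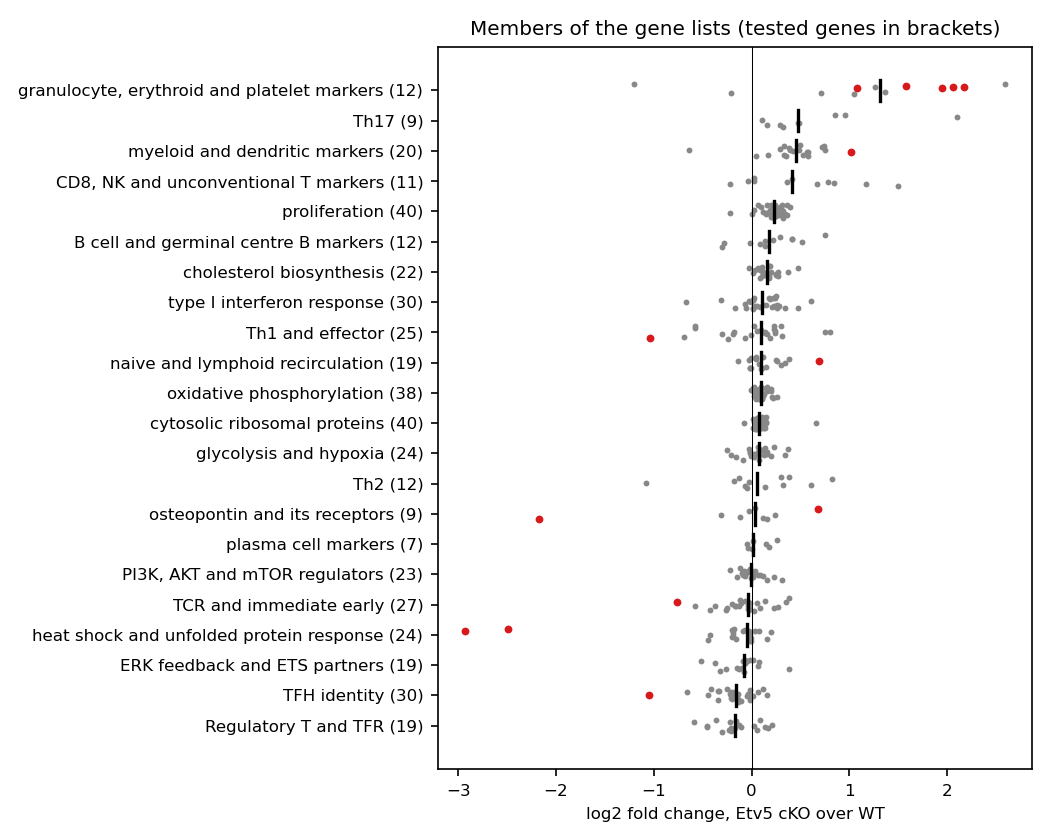
Log2 fold change (Etv5 cKO over WT, horizontal) of each tested member of the gene lists with at least 5 tested genes; grey points did not pass and red points passed an adjusted p of 0.05, black bars are medians, and brackets give the number of tested genes. Medians run from -0.17 for the regulatory T genes to 1.32 for the granulocyte, erythroid and platelet markers.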

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

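The selection behind this part was chosen after the table was seen, and no test was run on these genes. The authors did not test 12427 genes, and 4 of these are listed at 0 in WT and at 1 FPKM or more in Etv5 cKO: Snora34 (39.6 FPKM), Gm12238 (31.3 FPKM), Snora7a (12.7 FPKM) and Mir8091 (8.22 FPKM). The opposite case, at least 1 FPKM in WT and listed at 0 in Etv5 cKO, holds for 6 untested genes, all micro or small nucleolar RNAs, among them Mir8103 (273 FPKM) and Mir6363 (74.2 FPKM). FPKM values of such short genes are unstable, so these entries do not establish a difference between the genotypes.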

How the results depend on the processing

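No paired analysis was possible because the table holds 1 value per genotype and no library values; for the same reason leaving out a library, edgeR, DESeq2, limma with or without a trend, fry and camera with an estimated correlation were not run. Of the 40 called genes, 32 were kept when p was adjusted over every listed gene (Il7r, Itgb3, Lyz2, Fosb, Ier5l, Cpne7, Esm1 and Slc37a2 were lost), 31 among genes with at least 5 FPKM and 40 with at least 1 FPKM in a group (the last added after seeing the data). Adjusting over every listed gene adds 12427 genes that were not tested. It raises the adjusted p of all called genes by a common factor, so it acts as a stricter threshold and adds no evidence on a single gene. An unadjusted p below 0.01 with a 2-fold change gave 75 genes (35 higher, 40 lower), of which 32 were among the 40. Without Y-linked and erythroid genes, a choice made after seeing the data, the higher genes went from 12 to 5. The Etv5 log2 fold change was -1.31 as deposited, -1.27 and -0.52 with pseudocounts of 0.1 and 5, since 5 is close to its level, and -1.30 after quantile normalization or median centring. A pseudocount of 1, added after seeing the data, moved 11 of the 126 other genes that were called or named by the rule, and that of 5 moved 30. The 14 lists that passed the set test became 10 at a correlation of 0.05 and 7 at 0.1, both within the 14: the granulocyte and erythroid, myeloid, CD8 and NK, proliferation, heat shock, Th17 and TFH lists passed at 0.1. They became 16 on ranks (13 shared), 13 on log2(FPKM + 1) folds (12 shared), 11 among genes with at least 5 FPKM (11 shared; the Th17, CD8 and NK, and plasma cell lists then had too few genes) and 17 by random lists (13 shared); all of these but the 5 FPKM filter were added after seeing the data. The ERK and glycolysis lists were gained on ranks and by random lists, the B cell list on ranks, on folds and by random lists, and the Th1 list by random lists. The T cell receptor and immediate early list was lost on ranks and on folds, the interferon list on folds and with the 5 FPKM filter, and the ribosomal list by random lists. Directions of 3 lists reversed, each time without passing: Th1 (adjusted p = 0.938 on folds and 0.967 with the filter), PI3K (0.938 and 0.985) and osteopontin (0.804 on ranks). By random lists the Th1 median of 0.10 lay at the 99.9th percentile, although its mean was 0.00. The deposited p-values are shifted towards 1: 278 of 11569 were below 0.05, against 578 for uniform values, and their median was 0.704, so the 40 calls say little about genes that did not pass.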

Other observations

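Outside the fixed lists, 70 tested genes had an unadjusted p below 0.01 without passing adjustment, 23 higher and 47 lower in Etv5 cKO. Those with lower values included Malt1, a paracaspase of T cell receptor signalling (119 and 81.8 FPKM), the integrin chain Itgb8 (11.8 and 7.17 FPKM), the neurotrophin receptor Ntrk3 (23.0 and 15.8 FPKM) and Klf4 (6.21 and 3.62 FPKM). Those with higher values included genes known from myeloid cells, such as Plac8 (9.73 and 17.3 FPKM), Slpi (10.4 and 18.1 FPKM) and Siglec1 (0.333 and 0.721 FPKM), but Cybb, another such gene, had a lower value (19.8 and 13.6 FPKM). These genes were chosen after their values were seen.

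The tests of the following paragraphs were chosen after the result was seen, except those on erythroid genes not looked at before and on pan T cell genes.

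The 4 Y-linked genes fell to between 39.2% and 43.0% of the WT level. A larger share of female cells in the Etv5 cKO material is a candidate explanation: it needs a higher Xist, and the Xist log2 fold change was 0.64. The 4 X-linked escape genes examined beside Xist were above 0, but none passed. Mid1 and Gpm6b, called genes that also lie on the X chromosome, were lower (log2 fold changes -1.01 and -0.76). Both groups held Xist and Y-linked RNA, so each may have mixed male and female cells. If both kinds of RNA scale with cell number, the female share comes to 50.5% to 52.1% in WT and 78.7% to 81.2% in Etv5 cKO, depending on the Y gene used. All of these estimates use the same Xist values. Their range therefore shows only how far the Y genes differ, and the error of the share is unknown. A lower transcription of Y-linked genes without Etv5 stays open, since Xist did not pass adjustment, and no value per sex shows how far the other called genes depend on sex.

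Most tested members of the mixed granulocyte, erythroid and platelet list (10 of 12) and of the myeloid list (19 of 20) were higher in Etv5 cKO. Granulocyte genes were not tested apart from the mixed list. A lower share of T cells, with every other cell type up alike, was examined with the B cell list. The median of the erythroid, granulocyte and platelet list exceeded that of the B cell list by 1.14 on the log2 scale. The 95% range over resampled members was 0.61 to 1.83. The B cell median was itself 0.18, with 9 members higher, such as Cd79a (0.52) and Ly6d (0.75), and 3 lower, such as Cd22 (-0.28). Which cells carried these transcripts was not tested, and list members are not replicates. The comparison therefore leaves a lower share of T cells open. Carried-over erythroid cells or their RNA, which a sort on CD4 should remove, may be the source, and 11 erythroid genes not looked at before had a median log2 fold change of 0.48, above all 10000 random lists but short of the 0.5 set in advance, so this stays open. In the wider erythroid list, of which 32 tested genes were above 0 in WT and 6 are also in the list fixed beforehand, 31 of 32 genes were higher, the most abundant being Hbb-b1 and Hbb-bs at 279 FPKM in Etv5 cKO. Transcription of erythroid genes by the T cells themselves cannot be told apart from this, because a pool gives no value per cell.

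Hspa1a and Hspa1b were 2 of the most reduced transcripts. Reads passing from either copy to the other are argued against by the fall of both genes. Their sum fell by 2.58 on the log2 scale, which follows from those falls and is no separate test. A heat shock response that differed between the preparations is a candidate explanation: 16 other HSF1 target and chaperone genes had a median log2 fold change of -0.12, below all but 0.01% of matched random lists. Random lists draw genes independently, and the pan T cell list, with a median of -0.086, also lay below all of its matched random lists. The percentile is therefore not specific to a heat shock response. Whether such a response came from handling, from the sort or from the genotype was not tested, since each genotype has 1 value.

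Whether the lower TFH identity genes may reflect dilution of the T cells by other cells was tested with 20 pan T cell genes. Their median log2 fold change was -0.086, which was 0.068 above that of the TFH genes, with a 95% range over resampled members of -0.013 to 0.168. The test leaves dilution open. Rgs16, with a log2 fold change of -1.05, fell by far more than the pan T cell median.

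Slc15a2 lies within 20 Mb of Etv5 on chromosome 16, which raised the hypothesis of a chromosome segment carried along with the floxed allele. Of 238 tested genes in that window 4 were below an unadjusted p of 0.05 (Cd80, Fam43a, Slc15a2 and Stfa3), a share of 1.68% (exact 95% interval 0.460% to 4.25%), against 2.35% of other autosomal genes (Fisher's exact test, one-sided p = 0.811). The test found no excess, although the interval does not exclude a small one. By their labels both genotypes carry the floxed allele, so a segment linked to it would be present in both groups. The design therefore argues against this hypothesis.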
